A study of Homo sapiens with 4 samples.

How the data were processed

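Per the labels, RNA was measured in MDA-MB-231 cells, an established line of triple-negative breast carcinoma that was derived from a pleural effusion. Stable lines carried either the empty pcDNA plasmid or the same plasmid with FLAG-tagged wildtype LKB1, the serine/threonine kinase encoded by STK11. There were 4 libraries in 2 groups, 2 from the vector line and 2 from the LKB1 line. Total RNA was taken from cells on plastic dishes and made into libraries by a stranded whole-transcriptome method. The labels do not say whether the duplicates of a line were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Of the 4 libraries, 3 share a run tag in their titles and 1 LKB1 library carries another, and neither the run nor any other batch could be tested. The titles of the LKB1 libraries also carry the term fmRNA where those of the vector libraries carry mRNA; the labels do not say what this means, so a difference in preparation between the groups is not excluded.

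The data used here were a table of the authors' own comparison, with 34675 genes and no value per library. The submitters' processing notes name CASAVA 1.8.2, TopHat2 2.0.6, edgeR 2.6.0 and the build hg19, without saying what each was used for. How reads were counted, whether strand was used in counting, the annotation release and any filter are not given in the sources used here. Per the file headers, each gene had a fold change (a ratio), its log2, a p-value and an adjusted p-value, all as deposited by the authors. The adjusted p-values were the Benjamini-Hochberg adjustment over all 34675 genes, with a largest difference from a recomputed adjustment of 1.9e-06. Unless an assumed variation is named, the adjusted p of a single gene comes from the authors' deposited table and its test is not named in the sources used here. The header does not name the direction of the comparison. It was read as LKB1 over vector because the fold of STK11 was above 1, so every direction given rests on that reading, and the direction of STK11 itself is not independent evidence. A gene symbol that spreadsheet software had turned into a date was left as it stood.

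No library totals were given, but the fold column allowed the reads behind it to be recovered. A fold with a small prior count added to each group takes only certain values. Priors of 0.254868 reads in the LKB1 group and 0.245132 in the vector group, which sum to 0.5, resolved 26162 of the 28242 genes with reads (92.64%) into whole read totals per group below 3000 reads. Slightly altered constants matched 7 to 14 genes. The same constants give a depth of the LKB1 group of 1.04 times that of the vector group. In the table, 14387 genes had at least 40 reads over the 4 libraries and 11249 had at least 200, and the median of the protein-coding genes with reads was 456. These totals are sums over 2 libraries and carry no spread between them. Where a line had 1 to 3 reads the ratio is given with an exact (Clopper-Pearson) 95% interval, and where it had none the fold is a bound against 3 reads over the group. Such intervals and bounds cover counting error only.

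A gene was called changed at an adjusted p under 0.05. The rule for named genes was fixed before the data were examined: STK11, the 12 largest increases and the 12 largest decreases among called genes with a gene symbol and a mean of at least 50 reads per library, and up to 4 members with the smallest p from each list described. The part of the rule that asks for both LKB1 libraries on 1 side of both vector libraries could not be applied without values per library. Clone names were not counted as gene symbols. Some members that the rule names are not reported here. CXCR4, PTGS2, S100A4, EGFL7, FADS2, FASN, CCND2, CDK2, CDT1, POLA1 and the genes of the closing section were chosen after their values were seen. Also fixed before the data were examined were 42 gene lists. The list test planned for values per library could not be run. In its place, the mean rank of the log2 folds of a list's members with at least 40 reads was set against 10000 random lists matched on read total in 20 bins, two-sided, with Benjamini-Hochberg adjustment over the 41 lists with enough members. A second, one-sided comparison counted called members against the same random lists. Both are descriptions across genes, which are not independent replicates, and both take no account of correlation between genes. The smallest unadjusted p these random lists can give is 0.0001.

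Regions were sought among 10289 protein-coding genes with at least 200 reads. Medians of the log2 fold in windows of 25 neighbouring genes were taken after removal of a trend with GC content in 20 bins and transcript length in 5 bins. Windows beyond the 95th percentile of the largest window in 1000 permuted gene orders were joined into segments. GC content, transcript length and current names came from GENCODE 29 transcripts, matched by Ensembl identifier, and 98.7% of the protein-coding genes with 200 reads had a value. Coordinates are those of the authors' deposited table on hg19. A conditional negative binomial test on the recovered totals, with a coefficient of variation of 0.2 or 0.4 between libraries assumed for every gene, served as an alternative; genes not resolved entered it at 3000 vector reads. The spread that the deposited p-values imply for a gene was found as the coefficient of variation at which that test returned the same p. It was sought only for genes with a low unadjusted p, and so does not describe genes in general.

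The recovery and the conditional negative binomial test, not the authors' own test, were tried on simulated data for LKB1 against vector. All simulated genes shared a single variation between libraries, which the test was given. It was close to the median of 0.102 implied by the deposited p-values at 1000 to 3000 reads. The median implied at 200 to 500 reads was larger, at 0.126, and larger variations were not simulated. Of 26162 simulated genes 200 were changed, drawn from those with at least 200 reads. All totals (100%) were recovered, but the same constants made and decoded the folds, so this tests the decoding alone. At a 1.5-fold change 40% of the changed genes were called, at 2-fold 96%, at 4-fold and 8-fold 100%, and 8 unchanged genes were called. Of 60 simulated lists without a shift 5 had an unadjusted p under 0.05, as did 20 of 20 lists shifted by 0.5 on the log2 scale. Calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9. Other alternatives were a fold bound of 2, adjustment over other sets of genes, a threshold of 0.01, leaving out segments or genes under 200 bp, and other backgrounds for the lists. A check for mixed-up samples was run on the recovered totals, with bounds chosen after the totals were seen. In it 1 of the 2 groups did not match the named cell line. This counts against the label of that group, and the cells are called here only what the labels call them.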

Results

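The comparison asks how expression of LKB1 from a plasmid goes with the transcriptome of MDA-MB-231 cells, a mesenchymal-like triple-negative breast cancer line. Total RNA of a stable LKB1 line and a stable vector line was sequenced, with 2 libraries each. Values are those of the authors' deposited table, which holds 1 comparison over the 4 libraries and does not name its direction; it was read as LKB1 over vector from STK11. Read totals are sums over the 2 libraries of a line, recovered from that table, and the depth of the LKB1 line was 1.04 times that of the vector line. The cells are named here as the labels name them; in a check for mixed-up samples 1 of the 2 groups did not match the named cell line, and this applies to every difference below.

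STK11 (ENSG00000118046.10, chromosome 19, 1189406 to 1228428, plus strand, hg19), which encodes LKB1, was 1.54-fold higher in the LKB1 line in the authors' deposited table (log2 0.62, adjusted p = 0.00105), with 1321 reads in the vector line and 2112 in the LKB1 line. Reads of the plasmid and of the endogenous gene cannot be separated in this total. The 24 genes nearest to it (676392 to 1513603) had a median log2 fold of 0.19, the highest of them 0.67, and 2 of them passed the test. The call of STK11 was lost when a variation of 0.2 between libraries was assumed for every gene (adjusted p = 0.551), an alternative chosen after seeing the data. The reading of every direction given here rests on this same fold.

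The collagenase gene MMP1 and the ETS factor gene SPDEF were among the genes that fell most in the LKB1 line. The microRNA gene MIR221 and the neurotrophin receptor gene NGFR were among those that rose most. In the authors' deposited table, 2007 of 34675 genes had an adjusted p under 0.05, of which 884 were higher and 1123 lower in the LKB1 line. At a fold of at least 2 the counts were 341 higher and 691 lower, and at a fold of at least 4 they were 118 and 385. Among the called genes with at least 200 reads 698 were higher and 656 lower, whereas among those with fewer reads 186 were higher and 467 lower. Of those with at least 200 reads, 539 rose and 424 fell by a fold under 2. At a fold of at least 2, 159 of them rose and 232 fell, so the excess of decreases also goes with fold size. No read was found in the LKB1 line for 56 called genes and none in the vector line for 23.

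The largest decrease by the rule for named genes was that of CHRDL1, an antagonist of bone morphogenetic proteins, with 238 reads in the vector line and 1 in the LKB1 line, a ratio of 247 with a counting interval of 44.0 to 9810. The kinase gene NRK followed with 276 and 2 reads (ratio 143, interval 39.3 to 1190). MMP1, the interstitial collagenase, was 100-fold lower in the authors' deposited table (log2 -6.65, adjusted p = 1.35e-63), with 411 reads against 4. The zinc finger factor ZNF521 was 46.5-fold lower, the non-coding LINC00261 40.6-fold and the ubiquitin hydrolase UCHL1 39.8-fold. SPDEF, an ETS factor of luminal and secretory epithelium, fell 38.1-fold from 816 to 22 reads (adjusted p = 3.35e-76). The desmosomal cadherin DSC2 was 35.3-fold lower, the heparan sulfate 6-O-endosulfatase SULF1 33.5-fold, FAM155A 29.2-fold, the lipid flippase ATP10A 28.4-fold and the retinoic acid receptor RARB 27.8-fold. Outside the rule and chosen after its values were seen, RP11-181K12.2, an antisense transcript on chromosome 4, had 549 reads in the vector line and 0 in the LKB1 line, at least 190-fold lower; its implied variation between libraries was 0.436, at percentile 100 of called protein-coding genes of like totals, whose median was 0.112.

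Of the 12 largest increases 4 were microRNA genes, whose totals do not tell precursors from mature microRNAs or longer transcripts. MIRLET7C had 2 reads in the vector line and 288 in the LKB1 line (ratio 138, interval 38.0 to 1150), MIR221 3 and 416 (ratio 133, interval 45.3 to 649) and MIR99B 3 and 243 (ratio 77.9, interval 26.3 to 380). MIR222, the neighbour of MIR221 on the X chromosome, was 22.0-fold higher in the authors' deposited table. The variation between libraries implied by the deposited p-values lay at percentile 99.3 for MIRLET7C and 96.9 for MIR222 among called protein-coding genes of like totals. All 95 microRNA genes with at least 20 reads had a median log2 fold of 0.21 with 53.7% above 0, and 266 small nucleolar RNA genes one of 0.20 with 73.7% above 0. Among protein-coding genes, the leukotriene-forming lipoxygenase ALOX5 was 9.2-fold higher, the neurotrophin receptor NGFR 7.75-fold (207 against 1670 reads, adjusted p = 1.27e-55) and the Hedgehog effector GLI2 7.45-fold. TP53I11 was 6.46-fold higher, the non-coding DGCR5 6.39-fold, the calcium pump ATP2B2 6.28-fold, the ceramide synthase CERS4 6.14-fold and the mucin MUC4 5.91-fold.

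**Figure D1:**
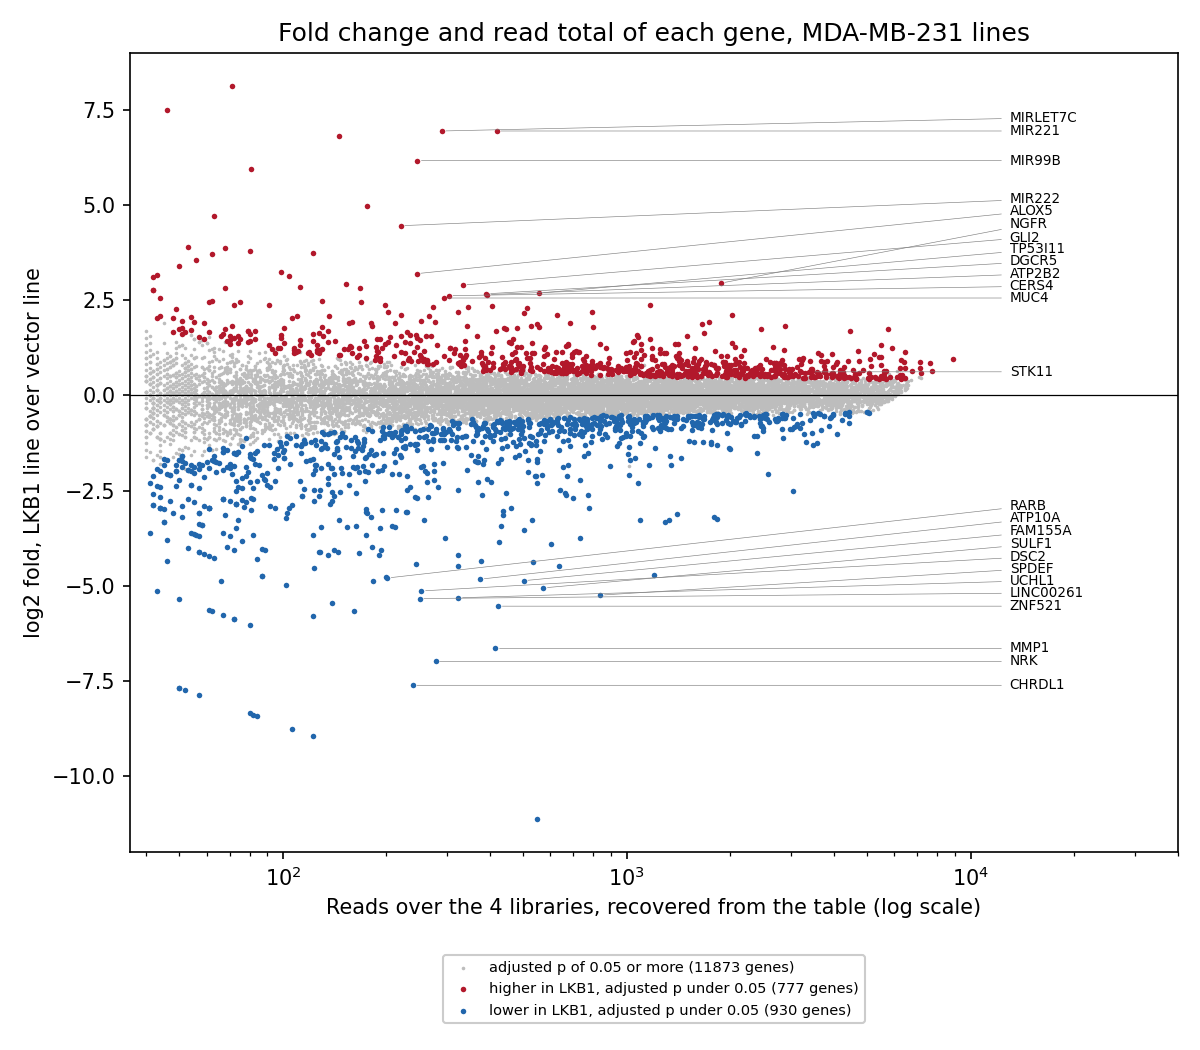
Each point is a gene with at least 40 recovered reads; the horizontal axis gives its reads over the 4 libraries on a log scale and the vertical axis the log2 fold of the LKB1 line over the vector line from the authors' deposited table, red and blue where the adjusted p is under 0.05. The labelled genes are those named by size and STK11, which lies at 0.62, close to the unchanged genes in grey, while MMP1 lies at -6.65.

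Genes described for lung and bone metastasis of MDA-MB-231 cells were lower in the LKB1 line as a group. Of 28 measured members 16 fell and 1 rose, and adjusted over the list alone 18 fell and 2 rose. The median log2 fold was -1.16, below that of all 10000 matched random lists, with an adjusted p of 0.00205 over 41 lists. Besides MMP1, the cytokine IL11 had a log2 fold of -3.24 (1650 to 181 reads, adjusted p = 1.39e-62), the matrix glycoprotein SPARC one of -4.49 and the protease ADAMTS1 one of -2.61 in the authors' deposited table. The chemokine receptor CXCR4 and the cyclooxygenase PTGS2 had log2 folds of -2.70 and -5.79, PTGS2 with 120 and 2 reads (ratio 62.4, interval 16.9 to 521). S100A4, a calcium-binding protein, rose by 1.13. None of the 16 members lay in a segment of neighbouring genes shifted together. Endothelial markers fell alongside this and the other groups that fell, and 1 of the 2 groups did not match the named cell line in a check for mixed-up samples, as given with the cell type markers.

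Mesenchymal genes and factors of epithelial-mesenchymal transition fell in 10 of 23 members and rose in 2 (adjusted over the list alone 11 and 2, median log2 fold -0.31, adjusted p = 0.00205 in the rank test). Some lists share members, so their falls are not separate findings. SPARC is in the metastasis, mesenchymal and matrix lists, TNC in the mesenchymal and matrix lists, and DUSP1 in the metastasis and CREB lists. In the authors' deposited table the proteoglycan BGN was at -4.11, the factor TCF4 at -4.12 and tenascin TNC at -1.22. Collagens, laminins and matrix glycoproteins fell in 14 of 44 members and rose in 6 (adjusted over the list alone 16 and 8; median -0.20, adjusted p = 0.00943). COL5A2 was at -3.90 and the laminin chain LAMA4 at -2.28. With only genes of at least 200 reads, an alternative chosen after seeing the data, the adjusted p of this list was 0.0704. Integrins and cell adhesion molecules fell in 12 of 32 members and rose in 3 (adjusted over the list alone 14 and 6; median -0.30, adjusted p = 0.0414). Protocadherin PCDH7 was at -4.39 and the leukocyte integrin chain ITGB2 at -2.49, while PCDH1 rose by 1.78 and L1CAM by 1.17. This last call was lost in 4 of the 5 other list settings, with adjusted p of 0.0506 to 0.16. At an assumed variation of 0.2 between libraries 6 of the 23 mesenchymal, 11 of the 44 matrix and 9 of the 32 adhesion genes passed.

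Sterol and fatty acid synthesis genes fell in 11 of 37 members and rose in 1 (adjusted over the list alone 19 and 1; median log2 fold -0.44, adjusted p = 0.00205). In the authors' deposited table the fatty acid desaturase FADS2 was at -0.70 and the fatty acid synthase FASN at -0.66, while EBP, a sterol isomerase inside the X segment described below, rose by 0.85. CREB and CRTC targets fell in 7 of 23 members and rose in 2 (adjusted over the list alone 9 and 2; median -0.37, adjusted p = 0.00342). The phosphatase DUSP1 was at -2.10, the early response factor EGR1 at -2.11, the activin subunit INHBA at -2.41 and JUNB at -0.94. JUNB lies in the segment of chromosome 19 described below, and 5 of the 7 lower members lay outside all segments (adjusted p = 0.0143 without genes in segments). Receptor tyrosine kinase and MAPK feedback genes fell in 12 of 44 members and rose in 4 (adjusted over the list alone 14 and 5; median -0.22, adjusted p = 0.00943). FGF5 was at -2.48, the ERK phosphatases DUSP6 at -1.24 and DUSP4 at -1.16, and the ligand NRG1 at -1.37. With a variation of 0.2 assumed, chosen after seeing the data, 1 of the 37 sterol and fatty acid genes passed, 3 of the 23 CREB and CRTC targets, without JUNB (adjusted p = 0.094), and 7 of the 44 receptor and MAPK feedback genes. The fall of the endothelial markers and the group not matching the named line apply to these 3 lists as well.

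G1/S and DNA replication genes fell in 3 of 49 members and rose in 1 (adjusted over the list alone also 3 and 1; median log2 fold -0.09, adjusted p = 0.185). Named here after their values were seen, cyclin CCND2 was 16.3-fold lower in the authors' deposited table (82 to 5 reads, adjusted p = 4.24e-12), CDK2 was at -0.73, the licensing factor CDT1 at -0.61 and the polymerase subunit POLA1 at 0.92. CDT1 lies in a segment of chromosome 16 shifted down and POLA1 in the X segment, and outside segments 2 members fell and 0 rose. Of 47 members of G2/M and mitosis 1, the kinetochore gene NDC80, fell (log2 -0.51, adjusted p = 0.0308) and 46 did not pass, among them KIF20A at -0.46 (adjusted p = 0.0501 in the authors' deposited table). Adjusted over the list alone none passed, at a median of -0.11, and the rank test gave an adjusted p of 0.00943, which was 0.258 against random lists not matched on reads. Of 24 replication-dependent histone genes, a list drawn up to follow RNA quality, 1, HIST1H3D, fell (log2 -3.48). Adjusted over the list alone this was also 1, at a median of -0.13 and an adjusted p of the list of 0.00205 in the rank test. Another 4 members with fewer than 40 reads were called and lie outside these counts. Of all 44 protein-coding genes with a HIST symbol and at least 40 reads, 4 fell and 0 rose, HIST1H3D among them. The share of changed genes over all protein-coding genes would give 5.81. Glycolysis and lactate genes fell in 3 of 27 members and rose in 1 (adjusted over the list alone 4 and 2; median -0.09, adjusted p = 0.33). Hexokinase HK2 was at -1.12, the lactate transporter SLC16A1 at -3.62 (62 to 5 reads) and PFKFB4 at -0.76, and the pyruvate dehydrogenase subunit PDHA1, inside the X segment, rose by 0.68. Assuming a variation of 0.2, 1 of the 49 G1/S genes passed, namely CCND2, none of the 47 G2/M genes and 2 of the 27 glycolysis genes.

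In the LKB1 complex and AMPK subunits 3 of 11 members rose and 1 fell (adjusted over the list alone the same counts; median log2 fold 0.14, adjusted p = 0.236). Besides STK11 these were the AMPK subunit PRKAG2 at 0.73, the LKB1 partner STRADB at 1.05 and PRKAB2 at -0.74 in the authors' deposited table. PRKAG2 lies inside the segment of chromosome 7 described below, and none of the 4 passed with a variation of 0.2 assumed. Among 11 AMPK-related kinases SIK1 rose by 0.60 and BRSK1 fell by 1.75 (adjusted over the list alone also 1 and 1; median 0.08, adjusted p = 0.686); NUAK1 was at 0.36 (adjusted p = 0.189) and MARK1 at -0.87 (adjusted p = 0.241). Of these kinases 1, BRSK1, passed with a variation of 0.2 assumed.

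Epithelial junction and identity genes went both ways, with 7 of 36 members higher and 6 lower (adjusted over the list alone also 7 and 6; median log2 fold 0.06, adjusted p = 0.732). The count of 13 changed members exceeded that of random lists (adjusted p = 0.000911). Beside DSC2, the tight junction gene TJP3 fell by 1.89, while periplakin PPL rose by 1.88. Metalloproteases, the plasminogen system and their inhibitors split into 7 higher and 7 lower of 32 (adjusted over the list alone 7 and 10). Their median was 0.00, with an adjusted p of 0.998 in the rank test. The count of 14 changed members exceeded the 4.17 that random lists held on average (adjusted p = 0.000911 for the count). Beside MMP1 and ADAMTS1, MMP16 fell by 1.91 and ADAMTS12, in a segment of chromosome 5 shifted up, rose by 0.94 in the authors' deposited table. At an assumed variation of 0.2, 4 of the 36 epithelial and 6 of the 32 protease genes passed. The other 17 pathway lists, G1/S and DNA replication among them, had medians of -0.26 to 0.26 and adjusted p of the rank test of 0.0635 to 0.995. Of these 3 held more changed members than random lists.

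**Figure D2:**
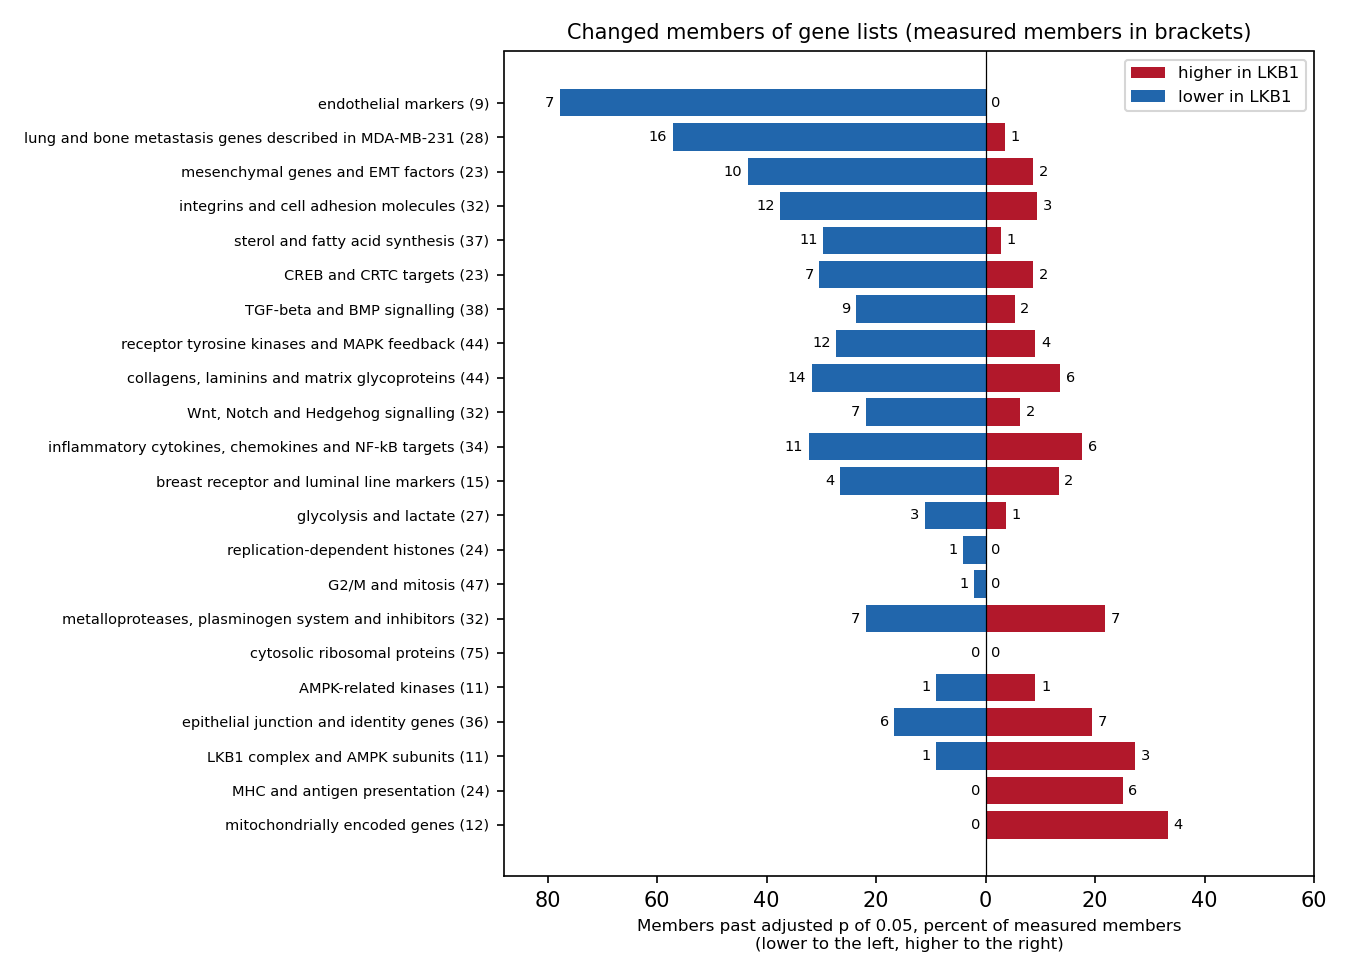
Bars give, for each gene list, the percent of its measured members (number in brackets) with an adjusted p under 0.05 in the authors' deposited table, to the left for members lower and to the right for members higher in the LKB1 line, with counts at the bar ends. The endothelial list has 7 of 9 members lower and the metastasis list 16 of 28.

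Markers of other cell types were examined as a check on the material. Endothelial markers were lower in the LKB1 line, with 7 of 9 members falling and none rising (adjusted over the list alone 8 and 1; median log2 fold -3.01, adjusted p = 0.00246). The adhesion molecule ESAM was at -3.27 (1197 to 129 reads), ENG at -3.01, VWF at -3.06 and the receptor TIE1 at -3.07 in the authors' deposited table, and EGFL7 was at 0.52 (adjusted p = 0.131). With only genes of at least 200 reads the adjusted p of this list was 0.16. Breast receptor and luminal markers fell in 4 of 15 members and rose in 2 (adjusted over the list alone the same). Their median was 0.11 and their mean -0.84, with an adjusted p of 0.833 in the rank test. The count of 6 changed members exceeded the 1.89 that random lists held on average (adjusted p = 0.0192 for the count). SPDEF and the secreted AGR2, at -4.11, fell, and the carbonic anhydrase CA12 at 1.37 and the oestrogen-responsive GREB1 at 1.81 rose. Basal markers MYLK and TRIM29 rose by 1.14 and 1.68, 2 of 7 members with none lower (adjusted over the list alone the same; median -0.14, mean 0.30, adjusted p = 0.797). Fibroblast markers COL6A3, COL3A1 and COL1A1 fell, at -1.28, -2.67 and -0.80, 3 of 7 members (adjusted over the list alone 3 lower and 1 higher; median -0.31, adjusted p = 0.424). Of 4 leukocyte markers LCP1 fell by 1.85 and CD14 rose by 1.04 (adjusted over the list alone also 1 and 1; median 0.12, adjusted p = 0.816). Of 6 neural and embryonic kidney markers UCHL1 and TUBB3 fell, at log2 folds of -5.32 and -0.50, and PAX8 rose by 0.96, TUBB3 lying in the segment of chromosome 16 (adjusted over the list alone 2 and 2; median 0.06, adjusted p = 0.816). When a variation of 0.2 was assumed, LCP1 and UCHL1 were the 1 member of each of these last lists to pass. Of the hepatocyte and intestinal markers only SERPINA1 was measured, at -0.46 (adjusted p = 0.204). In a check for mixed-up samples, 1 of the 2 groups did not match the named cell line.

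Lists that follow RNA quality and library type gave these values. The replication-dependent histones, given above with the cell cycle genes, belong here too. Their median log2 fold was -0.13, with an adjusted p of 0.00205 in the rank test. Mitochondrially encoded genes were higher in the LKB1 line, with 4 of 12 members rising and none falling (adjusted over the list alone 7 and 0; median log2 fold 0.39, adjusted p = 0.00703). MT-ND3 rose by 0.67, MT-CYB by 0.66, MT-ND2 by 0.53 and MT-CO3 by 0.45 in the authors' deposited table. None of these 4 passed with a variation of 0.2 assumed. Of 75 cytosolic ribosomal protein genes none passed, over all genes or adjusted over the list alone (median -0.02, adjusted p = 0.212). Of 28 small non-polyadenylated RNAs RNU4ATAC, of the minor spliceosome, rose by 0.84 (adjusted over the list alone also 1; median 0.13, adjusted p = 0.0927). Nuclear long non-coding RNAs rose in 3 of 14 members (adjusted over the list alone 4; median 0.09, adjusted p = 0.336), namely MALAT1 by 0.62, KCNQ1OT1 by 0.68 and LINC00657 by 0.44. Neither RNU4ATAC nor these 3 passed with a variation of 0.2 assumed.

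Neighbouring genes shifted together in several chromosome regions. The largest shift covered the short arm of the X chromosome from 2.8 to 54.6 Mb, where 118 genes had a median log2 fold of 0.75 (1.68-fold higher), 89.0% of them were above 0, 75 rose and 6 fell. STS, USP9X, CDK16 and AP1S2 had the smallest p there. On chromosome 19 from 11.5 to 19.2 Mb 132 genes had a median of -0.47 (1.39-fold lower), with 59 falling and 0 rising, among them ISYNA1, HAUS8, SYDE1 and KLF2. On chromosome 7 from 128.0 to 157.1 Mb 100 genes had a median of 0.39, with 33 rising and 0 falling, among them C7orf29, LRRC61, DGKI and PODXL. In all, 10 segments on 8 chromosomes passed the permutation threshold of 0.341, 7 of them higher and 3 lower. They held 540 of 10289 genes (5.25%), and 214 of the 1259 called genes of this set lay in a segment and went its way. MIR221 and MIR222 lie inside the X segment. These shifts, too, are between groups of which 1 of the 2 did not match the named cell line. The rank correlation of the log2 fold between neighbouring genes was 0.24, against at most 0.037 in permuted orders.

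**Figure D3:**
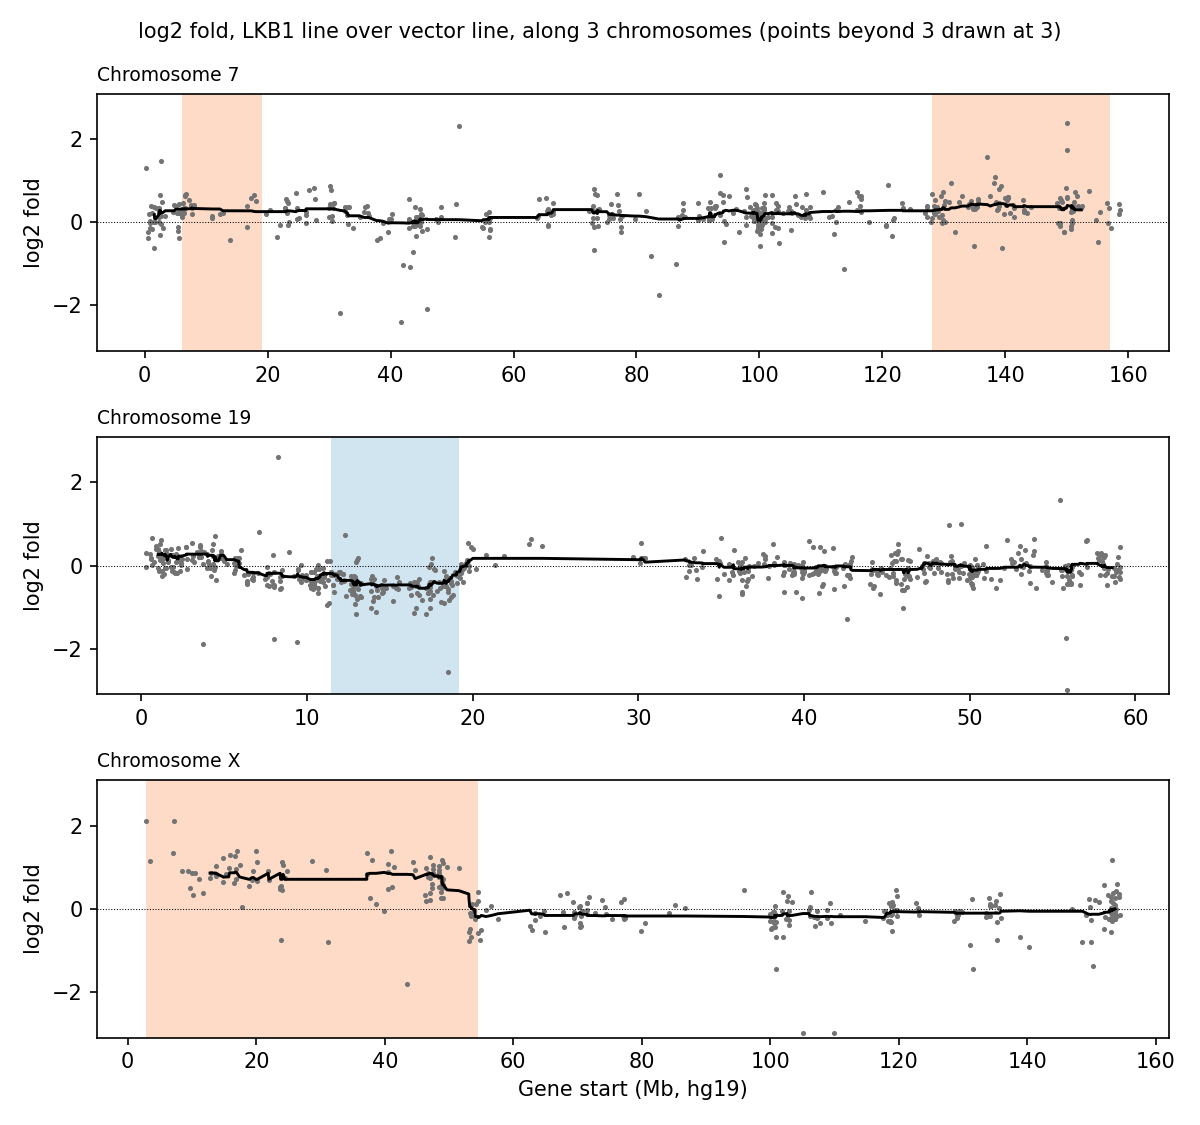
Points are protein-coding genes with at least 200 reads at their start on hg19 (Mb) with the log2 fold of the LKB1 line over the vector line from the authors' deposited table, points beyond 3 drawn at 3; the black line is the median of windows of 25 genes after removal of a GC and transcript length trend, and shading marks segments higher (red) or lower (blue). The X segment has a median of 0.75 and that of chromosome 19 a median of -0.47.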

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

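All alternatives except the fold bound of 2 and the adjustment over genes with any read or with at least 200 reads were chosen after seeing the data. The count of 2007 changed genes was 1032 with the fold bound of 2 (33.0% higher, against 44.0% of all), and 869 (32.1% higher, 864 of them shared) and 266 (18.4% higher, all shared) with a variation of 0.2 and 0.4 assumed for every gene; the cause of these losses was not tested. In other adjustments and gene sets it was 1663 to 2120, and at the stricter threshold of 0.01 it was 1370. STK11, at a log2 fold of 0.62, lay below the fold bound, and its adjusted p was 0.551 and 1 at the assumed variations of 0.2 and 0.4. The 24 other genes named by size passed in each alternative that tested them. The median variation implied by the deposited p-values was 0.191 at 20 to 100 reads and 0.102 at 1000 to 3000. It covers only genes with a low unadjusted p and rests on the test chosen here, so it is not the authors' own estimate. For such genes with many reads, 0.2 is wider than this implied variation. At 0.2 the changed members moved by over 1.5 times in 33 of 42 lists, and the number of lower members was 15 against 16 for metastasis, 7 in both for endothelial and 1 against 11 for sterol genes. Of 41 lists 11 passed the rank test, and 8 to 12 did in its alternatives. Among those not passing in every setting, MHC and antigen presentation genes (adjusted p = 0.0635) passed in 4 of 5 alternatives at 0.0248 to 0.0427, and small non-polyadenylated RNAs passed at 0.0324 against unmatched lists. Recentring on other gene sets moved log2 folds by at most 0.022 in size. At so small a shift it was set beforehand that 0 called genes changed sign. No paired analysis was possible because the table carries no value per library. For the same reason other size factors, library totals, the exact, quasi-likelihood and Wald tests, voom, leaving out each library, the index block, other pseudocounts and filters on low values, and the planned set tests were not run. The median protein-coding gene with reads had 456 reads. In simulated data 40% of 1.5-fold changes were called. This was by the conditional test with a known variation close to 0.102, and not by the authors' test. Depth was not varied there, so whether depth or variation between libraries limits such calls was not tested.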

Other observations

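The tests on small nucleolar RNAs, on the gap between microRNAs and their hosts, on implied variation, on the GC trend of segments, on X inactivation and on read levels of metastasis genes were chosen only after results were seen.

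Inflammatory cytokines, chemokines and NF-kB targets changed in both directions, with 11 of 34 members lower and 6 higher in the LKB1 line (adjusted over the list alone 15 and 6; adjusted p = 0.000683 for the count). IL8 was at a log2 fold of -1.82, CXCL1 at -2.11 and CSF3 at -3.67 in the authors' deposited table, and IL32 rose by 1.43; 10 of the 34 passed with a variation of 0.2 assumed. TGF-beta and BMP signalling genes fell in 9 of 38 members and rose in 2 (adjusted over the list alone 10 and 3), with BMP6 at -3.44 and BMP4 at 0.88; 5 of the 38 passed at that variation. Wnt, Notch and Hedgehog genes fell in 7 of 32 members and rose in 2 (adjusted over the list alone 8 and 3), with the receptor FZD8 at -3.75 and LEF1 at -2.07. MHC and antigen presentation genes rose in 6 of 24 members and fell in none (adjusted over the list alone 8 and 2), with HLA-B at 0.80, HLA-C at 0.72 and B2M at 0.57; the HLA genes share similar sequence, so reads may be split between them, and none passed with a variation of 0.2 assumed, where 0 members changed.

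All 13 measured protocadherin alpha genes (PCDHA) were lower, at a median log2 fold of -2.96. These genes share their last exons, and PCDHA2, PCDHA3 and PCDHA4 had the same totals of 64 and 9 reads, so the 13 are uncertain as separate genes. MSI2, an RNA-binding protein gene chosen after its values were seen, had 1154 and 45 reads, 26.5-fold lower. Among microRNA genes with at least 20 reads 26 rose and 5 fell of 95.

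A set of microRNA genes rose in the LKB1 line. Whether their reads came from precursors, mature microRNAs or longer transcripts was not measured. The 13 called ones that lie inside a longer transcript, picked for being called, had a median log2 fold of 3.92. Over all 95 microRNA genes the median was 0.21, with 53.7% above 0. Higher transcription of the hosts as the whole of the rise is argued against for the group. The hosts, not picked by their own values, reached at most 1.73 and lay below these microRNAs by a median of 3.75. For AL161772.1, at 1.95, the gap to its host IL17D, at 1.73, was only 0.22. A part stays open for the others, as the 12 hosts had a median of 0.39 and 5 of them rose. The 50 other microRNA genes with a host differed from it by a median of -0.03. This gap decides nothing, since reads of a host may be counted for both. Reads from 1 LKB1 library alone cannot be excluded without values per library. The implied variation of the group lay at a median percentile of 53.7 of called protein-coding genes of like totals. It was at or above percentile 95 for 5 of 26, MIRLET7C and MIR222 among them. Whether this measure would reveal reads from a single library was not tested, so it draws no conclusion. Short inserts retained in the LKB1 libraries are a candidate explanation, as 73.7% of small nucleolar RNA genes were above 0, though their median log2 fold was only 0.20. Other non-coding classes differed. The share above 0 was 92.3% of 13 mitochondrial transfer RNA genes, 58.0% of 50 small nuclear RNA genes and 58.8% of 68 miscellaneous RNA genes. It was 34.0% of 47 ribosomal RNA genes, so these classes did not all rise. Library titles (fmRNA in the LKB1 group, mRNA in the vector group) differ in a way the labels do not explain, and an effect of LKB1 on microRNAs stays open, untested.

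For the blocks of neighbouring genes, 12 segments were found with the trend of GC content and transcript length left in. These segments kept a median of 0.87 of their shift after its removal (0.76 to 1.22). This draws no conclusion, since removing so small a trend could hardly have taken the shifts away. The median log2 fold ran only from 0.066 in the genes lowest in GC content to -0.082 in those highest. The GC trend was thus smaller than the shifts, the smallest of which was -0.24. A change of X inactivation over the whole X is argued against as the cause of the X segment. Of the 90 X genes left out of the search described next and outside its X segment, 27 (30%) were above 0. As they lie beyond a segment picked for being high, that share is pulled down and does not decide alone. All 317 protein-coding X genes with at least 200 reads, segment included, had a median log2 fold of only 0.049, with 79 rising and 21 falling. A separate search on every other gene gave 7 segments, in which 85.7% of 343 left-out genes went the segment's way, with a median of 0.91 of the shift of the genes used. The left-out genes lie between the genes used, so this shows only that the shifts are regional. A copy number difference between the stable lines is a candidate explanation that this search cannot tell from other regional causes. That search met 6 of the 10 segments and missed 4, 2 of its 7 lay elsewhere, and in 2 of the 7 the shift fell short in the left-out genes (0.32 to 0.15 on chromosome 7 and 0.35 to 0.18 on chromosome 10). DNA was not measured and 1 of the 2 groups did not match the named line in the check for mixed-up samples, so other cells in 1 group and regional regulation stay open, as does any link to LKB1, since each plasmid is represented by a single line.

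For the fall of the metastasis genes, the shifted segments are argued against, with 0 of the 16 lower members in a segment shifted down. After removal of the GC and length trend the list median was -1.11 against -1.16. This removal draws no conclusion, since so small a trend could hardly have moved the median far. The median log2 fold ran only from 0.066 in the genes lowest in GC content to -0.082 in those highest. The GC trend was thus much smaller than the fall of the list. RNA of other cells in the libraries of 1 group cannot be told apart from a change within the line: 10 of the 16 had at least 500 reads in the vector line and 6 had fewer, endothelial markers fell alongside (ESAM from 1197 to 129 reads, VWF from 203 to 25), and 1 of the 2 groups did not match the named line in the check for mixed-up samples. Decreases exceeded increases among called genes with fewer than 200 reads, 467 against 186. They also did so among those with at least 200 reads and a fold of at least 2, 232 against 159. The cause of this excess is open in the same way. An effect of LKB1, and a difference between 2 separately grown lines that has nothing to do with it, stay open as untested.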
